A study of Gallus gallus with 8 samples.

How the data were processed

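Single-cell RNA sequencing (10x Genomics Chromium, 3′ chemistry, in which each captured transcript carries a unique molecular identifier, or UMI) was carried out on the branchial arches of wild-type chicken embryos. The labels describe 8 samples, a distal 20% and a proximal 80% portion of each of 4 arches. Arches 1 and 2 were taken at Hamburger-Hamilton stage 13 from 15 embryos, and arches 3 and 4 at stage 15 from 10 embryos, per the labels' protocols. Tissue of the same arch and portion was pooled before dissociation, so each sample is 1 pool and no combination of arch and portion has a second sample.

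The authors deposited 1 matrix of 17108 genes by 95109 cells. Its values are the natural log of 1 plus the UMIs per 10000 UMIs of the cell, as the deposited values themselves show. Brought back to the linear scale they summed to 10000 in each cell, and all 95930467 values above 0 (100%) were whole multiples of the smallest value in their cell within a tolerance of 0.01. The UMIs of each cell were therefore recovered by dividing by that smallest value. The submitters' processing notes name bcl2fastq 2.20, Cell Ranger 2.1.0, Seurat 2.3.4 and the galGal4 build, with no role or order. The aligner settings, the annotation release and the cell filter are not given in the sources used here. In the matrix, no cell had fewer than 501 genes, and 2626 genes were at 0 in each cell, so genes without a UMI had not been removed.

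Cells were not assigned to samples. Column names are cell barcodes with a suffix from 1 to 8. By convention Cell Ranger writes such a suffix to keep libraries apart when it combines them, and no source used here states that this holds for this matrix. No label, header or file used here says which suffix belongs to which sample. The order of the suffixes, their cell numbers and their expression values were not used in place of such a map. The comparisons of distal with proximal portions, of arches and of stages that were fixed before the data were examined were therefore not made, and neither were their tests with limma and camera. The pooled matrix is 1 sample as far as the design goes. Each suffix was described as 1 library of unknown sample, and its values are given without a test, a standard deviation or a group. All 95109 columns were used as cells of the pooled matrix.

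Genes were not named. The matrix gives Ensembl identifiers only, and 0 of the 17108 identifiers matched a symbol in the table of 25635 genes used here (NCBI RefSeq, assembly GRCg7b). The cell type markers and gene lists fixed before the data were examined were therefore not applied, clusters carry numbers and no cell type, and the rule for named genes had nothing to act on. The 2 identifiers printed are the tested genes with the largest range over the suffixes, a rule chosen after the data were seen. No coordinates are given.

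Cells were clustered on the deposited log values. The 2000 genes with the highest dispersion within 20 bins of the mean were scaled to unit variance with a limit of 10, after genes with a mean of 0.125 or less had been left out, and 30 principal components were computed. The 15 nearest neighbours of each cell were found exactly, and the graph weighted by shared neighbours was partitioned by the Leiden method at resolution 1 with 10 iterations. Groups of fewer than 50 cells were left out of the account of clusters. Shares of cells in a cluster have exact (Clopper-Pearson) 95% binomial intervals, and UMI sums have exact 95% Poisson intervals. These intervals cover counting error only. Where a share was 0, the limit given is 3 cells of the suffix's total. Doublets were not removed. A doublet score was built from simulated sums of 2 cells of the same suffix. The scores of the simulated sums showed a valley in 2 of the 8 suffixes, where 42.2% and 64.9% of cells scored above it. In 6 suffixes no valley was found, so no cell was called a doublet. An alternative left out the 10% of cells with the highest score in each suffix.

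A gene's level in a suffix was the mean of its UMIs per 10000 over the suffix's cells. Genes with a mean of at least 0.1 in at least 2 suffixes were kept, and the range was taken on log2(mean + 0.05), which understates the range of low genes. A range of at least 4-fold was counted. Levels at fixed cluster shares were computed from the clusters with at least 20 cells of every suffix, each weighted by its share of all cells in them. Within single clusters, those with at least 100 cells of every suffix were used, with a minimum mean of 0.5. Genes per cell were compared after each cell had been thinned at random to 1000 UMIs, which left out 4226 cells with fewer. Sets of co-varying genes were sought in these thinned cells among the 2554 genes with at least 0.05 UMIs per cell. Log values were centred within each cluster and suffix, genes correlated above 0.1 were linked, and connected sets of at least 5 genes were kept. Sets were found in 45451 cells and measured in 45357 others, beside 100 random sets per set matched on mean expression.

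The range count was tested on simulated UMI sums with the real totals. It recovered 100 of 100 genes changed 8-fold in 1 suffix and 100 of 100 changed 16-fold, and called 0 unchanged genes among 5762 kept. Both changes lay well above the 4-fold bound, and none nearer to it was simulated, so recovery there is unknown. Simulated sums also do not measure the spread between real libraries. The search for sets recovered a planted set of 20 genes among 2554 and added 0 others. All analyses of clusters, suffixes and gene sets took the place of the comparisons fixed before the data were examined and were chosen after seeing the data. Cluster numbers, the count of genes with a 4-fold range, the rate of shared barcodes and the distances between suffixes had been seen in exploratory passes before the final procedure was written. The correlation threshold of 0.1 was picked after several thresholds had been tried, the treatment of doublets was changed after the valley had failed, and the comparison within single clusters was added after the other results were known. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, scikit-image 0.26.0 and Matplotlib 3.10.9 were used. Alternatives varied the resolution, the number of variable genes and components, the pseudocount, the filter, the scaling, the averaging, the depth and the cells.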

Results

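The series profiled single cells of the chicken branchial arches, the paired swellings of the embryonic head and neck that are filled by migrating neural crest cells. Neural crest is the population that leaves the dorsal neural tube and gives rise to much of the facial skeleton and peripheral nervous system. The 8 samples covered the distal and proximal portions of arches 1 to 4, and the title of the series places the neural crest and its surrounding tissue at the centre. The comparisons this design implies are of the distal with the proximal cells of an arch, and of the arches with each other. Neither was made, because the cells carry no sample label in the sources used here. What follows describes the pooled cells and gives each barcode suffix as 1 library of unknown sample. That a suffix stands for 1 library is the usual convention of Cell Ranger, and no source used here states it for these cells.

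The matrix held 95109 cells, the number the design text states, and 240762754 UMIs. The median cell had 2155 UMIs and 945 genes, and cells spanned 670 to 19746 UMIs and 501 to 3498 genes. Of the 17108 genes, 14482 had a UMI in at least 1 cell. Suffixes 1 to 8 held 15723, 4159, 23544, 5963, 19607, 3293, 17120 and 5700 cells. Their total UMIs ran from 7735116 in suffix 6 to 66110217 in suffix 3. The median UMIs per cell lay between 1920 in suffix 4 and 2454 in suffix 3. Once each cell was thinned to 1000 UMIs, the median number of genes per cell lay between 526 in suffix 4 and 567 in suffix 7, against 830 in suffix 4 and 1033 in suffix 3 before thinning.

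**Figure D1:**
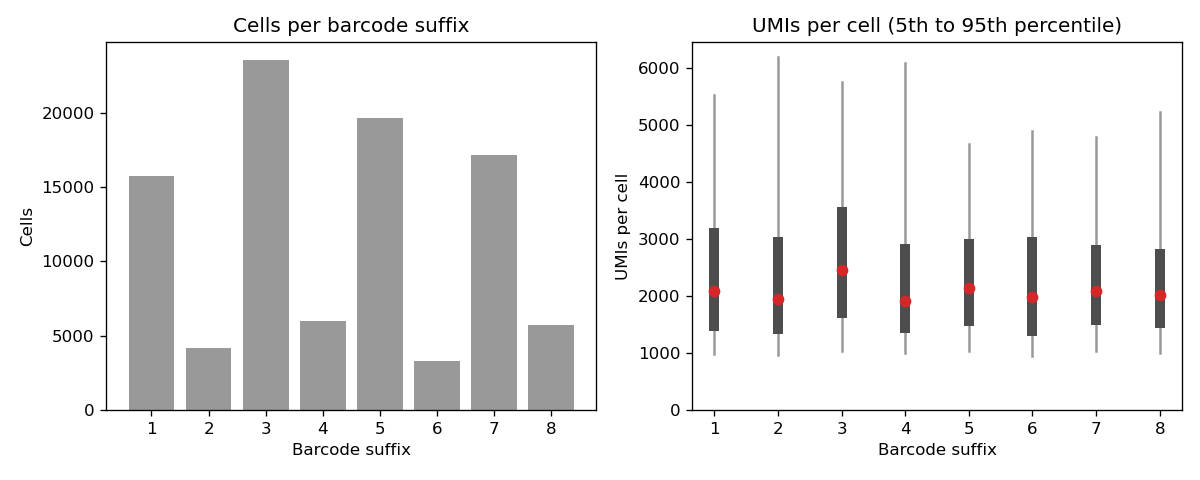
Cells per barcode suffix (left, bars) and UMIs per cell (right, with the median as a red point, the middle 50% as a thick bar and the 5th to 95th percentile as a thin line). Cell numbers ran from 3293 to 23544, while the medians of UMIs per cell stayed between 1920 and 2454.

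The cells fell into 19 clusters of 1568 to 7851 cells, with 80 further cells in smaller groups. At resolution 2 they fell into 36. No cluster held more than 8.25% of the cells. In none of the 19 did a single gene supply more than 2.41% of the UMIs. The clusters' median depth ran from 1263 UMIs in cluster 1 to 3486 in cluster 8. Cluster 8 also had the highest median number of genes, 1374, and cluster 1 the lowest, 621. The clusters were not given cell types.

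The make-up of the suffixes differed well beyond counting error. Only clusters 6 and 7 held at least 1% of the cells of every suffix, a count that lay between 0 and 4 under other settings of the clustering. Cluster 7 took from 3.53% (95% interval 3.25 to 3.83) of the cells of suffix 1 to 27.1% (25.6 to 28.6) of those of suffix 6. Cluster 10 took 0.361% (0.288 to 0.446) of suffix 3 and 27.3% (26.2 to 28.5) of suffix 8. Cluster 13 was rarest in suffix 3 at 0.0127% (0.00263 to 0.0372) and made up 22.5% (21.4 to 23.6) of suffix 8. Cluster 3 held 27.8% (27.1 to 28.5) of suffix 7 and 0.0240% (0.000609 to 0.134) of suffix 2. Cluster 2 held 20.0% of both suffix 1 and suffix 2 and 0.281% (0.161 to 0.455) of suffix 8.

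Cluster 18 was concentrated most strongly. With the suffixes weighted equally, suffix 3 supplied 75.6% of it, and cluster 3 followed with 66.7% from suffix 7. Cluster 3 also made up 12.9% of suffix 5, and at most 0.333% of any suffix other than 5 and 7. A cluster held mostly by 1 library can be a feature of that library and not a cell type, and the 2 were not told apart. A population particular to an arch or portion could not be told apart from these, since the suffixes have no sample. Cluster 18 had no cell among the 4159 of suffix 2, which allows a share of up to 0.0721%, and none among the 3293 of suffix 6, which allows up to 0.0911%. Cluster 8 had no cell among the 5700 of suffix 8, which allows up to 0.0526%, and made up 15.7% (15.2 to 16.2) of suffix 3. Cluster 19 was the most even, from 0.604% (0.423 to 0.835) in suffix 4 to 2.33% (2.1 to 2.58) in suffix 1. It was the single cluster whose share ranged less than 4-fold, whereas the shares of 14 clusters ranged more than 10-fold.

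**Figure D2:**
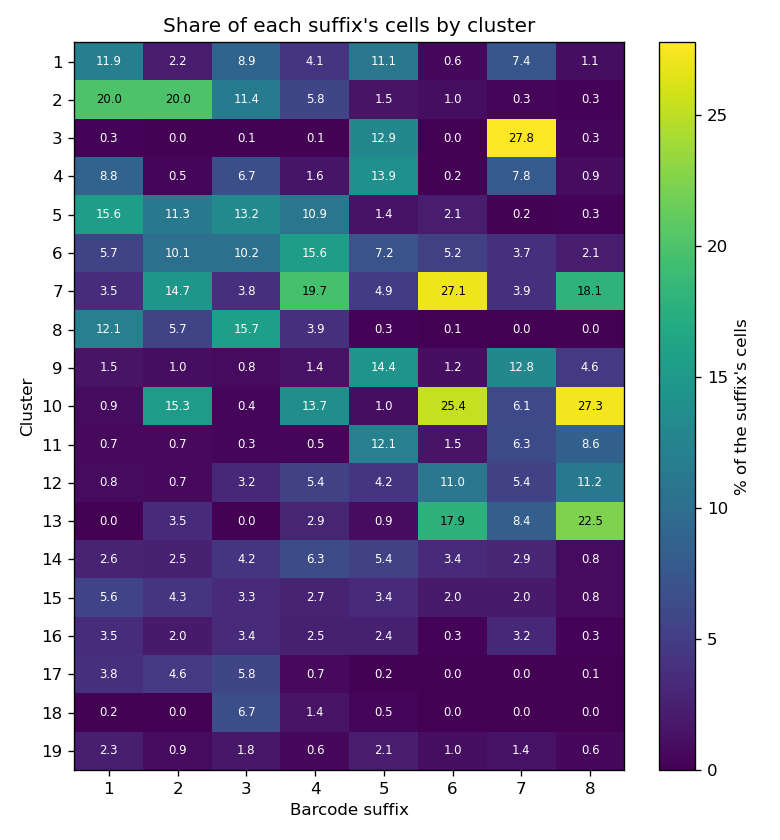
Percent of each suffix's cells (columns) in each of the 19 clusters (rows), with the values printed and coloured by size. The largest shares are 27.8% (cluster 3, suffix 7), 27.3% (cluster 10, suffix 8) and 27.1% (cluster 7, suffix 6).

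Gene levels also differed between the suffixes. Of 6065 genes tested, 959 ranged at least 2-fold, 225 (3.71%) at least 4-fold and 73 at least 8-fold, with a median range over all tested genes of 0.58 on the log2 scale. For each of the 225 genes the exact Poisson intervals of the highest and lowest suffix lay apart. The highest level fell most often in suffix 7 (60 genes) and suffix 6 (57 genes), and the lowest in suffix 1 (54 genes) and suffix 6 (46 genes). The count of 225 moved to 370 with a pseudocount of 0.01, to 28 with 0.5 and to 95 from the mean of log values. No test between suffixes was made, because each was taken as a single library.

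The largest range was that of ENSGALG00000008635, at 5.34 on the log2 scale. It was found at a mean of 2.02 UMIs per 10000 in suffix 2 (1834 UMIs), 1.22 in suffix 6 (922 UMIs) and 0.548 in suffix 4 (722 UMIs). In suffix 3 its mean was 0.00111, from 6 UMIs. Per 10000 of all UMIs of a suffix, its count was 1.75 (95% Poisson interval 1.67 to 1.83) in suffix 2 and 0.000908 (95% Poisson interval 0.000333 to 0.00198) in suffix 3. ENSGALG00000025730 followed with a range of 5.26. Its mean was 2.61 UMIs per 10000 in suffix 8, 2.08 in suffix 6 and 1.01 in suffix 7, and 0.0195 in suffix 3, where 132 UMIs were counted. Per 10000 of all UMIs, its count was 2.74 (95% Poisson interval 2.66 to 2.83) in suffix 8 and 0.020 (95% Poisson interval 0.0167 to 0.0237) in suffix 3.

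The ranges were computed again with the same make-up for every suffix. For this, 9 clusters, with 41452 cells (43.6%), had the needed 20 cells or more of every suffix. No interval is given for levels at fixed shares, and sampling of few cells can widen their ranges. At fixed cluster shares 120 of the 6065 genes ranged at least 4-fold, and 95 of these were among the 225. In the cells of the same 9 clusters, with the shares not fixed, 236 tested genes did. The count of 120 moved to 243, 12 and 34 under the same 3 settings. The median range of all tested genes was 0.58 on the log2 scale over all cells and 0.57 at fixed shares. ENSGALG00000008635 and ENSGALG00000025730 had ranges of 5.49 and 5.57 at fixed shares, while single levels moved further. The mean of ENSGALG00000008635 in suffix 6 was 0.381 UMIs per 10000 at fixed shares against 1.22 over all cells. That of ENSGALG00000025730 in suffix 7 was 2.55 against 1.01, which placed it above suffix 6 (1.76 against 2.08).

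**Figure D3:**
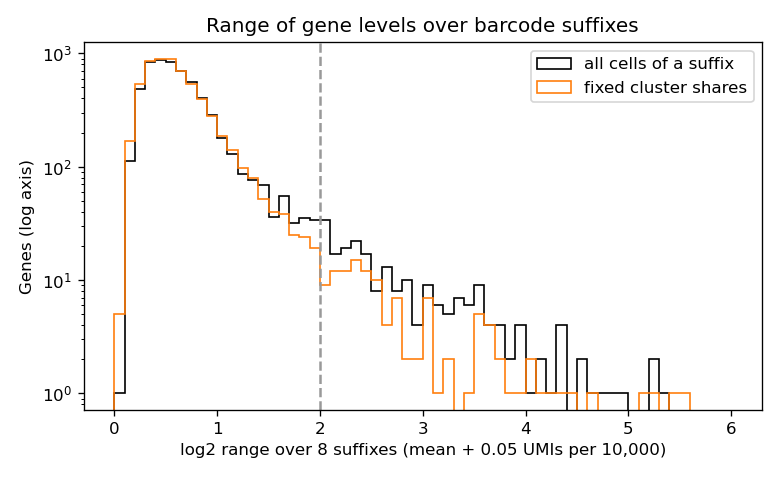
Number of genes (log axis) by the log2 range of their level over the 8 suffixes, for all cells of a suffix (black) and at fixed cluster shares (orange), with a dashed line at 4-fold. Beyond the line lie 225 genes over all cells and 120 at fixed shares.

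Within the clusters that had at least 100 cells of every suffix, ranges could be compared without a change of make-up between clusters. The minimum mean was set higher here than over all cells. In cluster 6 a range of at least 4-fold with intervals apart was seen for 99 of 2474 genes, and in cluster 7 for 95 of 2465. In each cluster, 51 of these genes also ranged at least 4-fold over all cells. The cells of a suffix numbered 119 to 2404 in cluster 6 and 555 to 1175 in cluster 7. The intervals leave out the spread between cells, so sampling of few cells can widen these ranges. Over the 2316 genes tested in both, 66 ranged in cluster 6 and 60 in cluster 7. Of these, 38 ranged in both, where independent lists of these sizes would share 1.71. Of the 38 genes, 22 had their highest level in the same suffix in both clusters. Genes are not independent replicates, and both clusters came from the same 8 libraries.

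Inside clusters and suffixes, 4 sets of genes, with 58 genes in all, were connected by pairwise correlations above 0.1 from cell to cell. A gene needed a link to only 1 other member, so the mean correlation of a set can lie below 0.1. The threshold of 0.1 was picked after several had been tried. A threshold of 0.08 gave 97 genes and one of 0.15 gave 13. The tightest had 13 genes, with a mean pairwise correlation of 0.37 to 0.49 over the 8 suffixes (median 0.44), measured in cells not used to find it, against 0.0077 in matched random sets. These 13 genes supplied 7.0% of UMIs on average, from 0.7% in the cell at the 5th percentile to 15.5% at the 95th. Their share was lowest in cluster 16 (2.23%) and highest in cluster 13 (12.1%). By suffix it ran from 4.55% in suffix 2 to 8.79% in suffix 5, and from 5.19% to 7.33% at fixed cluster shares.

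The other sets were looser, each with a median correlation below the 0.1 used to link pairs. A set of 24 genes supplied 11.7% of UMIs, with a median correlation of 0.067 over the suffixes against 0.017 in matched random sets. Its share differed less between clusters, from 9.12% in cluster 3 to 13.3% in cluster 7. A set of 15 genes had a median correlation of 0.089 against 0.0012, and supplied 0.341% of UMIs in cluster 15 and 0.619% in cluster 16. A set of 6 genes had a median correlation of 0.098 against 0.00086, and its share ran from 0.0250% in cluster 17 to 0.492% in cluster 15. None of the 58 genes was among the 225 that ranged at least 4-fold between suffixes. Those 225 were 3.71% of the 6065 genes tested. The 58 were sought among 2554 genes, for which this percentage was not computed, so no expected number is given. The lack of overlap was not read as a result.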

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

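No paired analysis was possible because the matrix columns carry no sample label, so the distal and proximal portions of an arch could not be matched, and every alternative planned for the comparisons between groups was not run for the same reason. All the alternatives given here were chosen after seeing the data. Of 53 alternative values, 40 stayed within 1.5 times the reported value. The number of clusters was 36 at resolution 2 in place of 19, and lay between 14 and 23 under the other settings. The agreement of the cells' clusters with the reported ones (adjusted Rand index) ran from 0.64 at resolution 2 to 0.83 without the top 10% of cells by doublet score. The count of clusters with at least 1% of every suffix, reported as 2, moved to 4 at resolution 0.5 and with 15 components, to 1 at resolution 2 and to 0 with 50 components, so it depends on both settings. The genes ranging at least 4-fold, reported as 225, numbered 370 with a pseudocount of 0.01, 28 with 0.5 and 95 from the mean of log values. At fixed cluster shares, reported as 120, the same settings gave 243, 12 and 34. A larger pseudocount shrinks the range of low genes by construction; for the mean of log values the cause was not tested. Leaving out each suffix in turn gave 176 to 217 genes, and 96 to 114 at fixed shares. The co-varying sets held 97 genes at a correlation above 0.08 and 13 above 0.15. Depth limited the levels of low genes: 9 of the 225 had 3 or fewer UMIs in at least 1 suffix.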

Other observations

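All the tests in this part were chosen after the patterns they bear on had been seen. The bounds for and against each explanation were written before the value of its test was seen, except for the test of UMIs per cell. That test and its bound were chosen after the results were known, in place of one by thinning that the scaling per cell made void.

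The 8 libraries of unknown sample were compared in pairs by their mean expression, and no clustering of the libraries was run. The root mean square difference in log2 level between 2 suffixes, over the 6065 genes, ran from 0.26 to 0.61 with a median of 0.43 over 28 pairs. Suffixes 1 and 3 were each other's nearest (0.26), as were 5 and 7 (0.27), 2 and 4 (0.32), and 6 and 8 (0.33). The second nearest lay at 0.30 for suffix 3, 0.30 for suffix 5, 0.35 for suffix 1, 0.38 for suffixes 2 and 4, 0.39 for suffix 6, 0.41 for suffix 8 and 0.42 for suffix 7. At fixed cluster shares the differences ran from 0.22 to 0.51, and only suffixes 5 and 7 remained each other's nearest (0.22). No sample was read from these values.

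Between-suffix ranges of 4-fold or more, seen for 225 genes, were weighed against technical explanations. Counting error in the UMI sums is argued against, since the intervals of the highest and lowest suffix lay apart for 100% of the genes. At these UMI totals a 4-fold range left little room for overlap, so the 100% adds little to the range itself. The intervals leave out the spread between cells and between libraries. A difference in UMIs per cell stays open by the median and by the mean of UMIs per cell. The median cannot decide it, because the shallowest suffix was a near tie. Suffixes 4, 2 and 6 had medians of 1920, 1940 and 1987. Suffix 3, the deepest by both, held an extreme of 50 genes (22.2%), where an even spread over the suffixes would give 25%. Suffix 4, the shallowest by the median, was highest for 10 genes and lowest for 13. Suffix 6, the shallowest by the mean, was highest for 57 genes and lowest for 46, above an even spread. Of the 225 genes, 0 had both extremes in the deepest and shallowest suffix by the median. By the mean 26 (11.6%) did, where an even spread would give 3.57%. The shares of the clusters stay open as a possible explanation for part of the genes. At fixed shares in 9 clusters, 42.2% still ranged at least 4-fold, below the bound of 50% set against it. Those clusters leave out 56.4% of the cells. The clusters were built on many of these genes, so a low percentage alone cannot decide the question. In the same 9 clusters without fixing the shares, 236 tested genes ranged at least 4-fold, against 120 at fixed shares. The 225 genes had been picked over all cells, and 149 of them (66.2%) still ranged at least 4-fold in these clusters without fixing the shares. The median log2 range of the 225, which is 2.57 over all cells, was 2.45 there and 1.80 at fixed shares. Arch, portion and stage, which the design names, stay open and untested, because the suffixes have no sample.

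Barcode sequences that occurred under more than 1 suffix gave a check on reads assigned to the wrong library, and no biological explanation was tested. The 95109 cells had 90249 distinct sequences and 5023 pairs of cells with one sequence. Of the 28 pairs of suffixes, 0 lay more than 2 Poisson standard deviations from the common rate. If molecules of one cell had been read in 2 libraries, such pairs would resemble each other more than random pairs from the same suffixes. Their median correlation was 0.608 against 0.606, a difference of 0.0016 that lies below the bound of 0.02 set against this explanation. This bears on the pairs as a whole, since a median would not show a small part of them coming from one cell. No cell in the matrix had fewer than 501 genes. A copy of a cell made of few molecules would therefore be missing from the matrix, and the check could not see it.

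Cluster 1, with 7851 cells and a median of 1263 UMIs, had the shallowest cells. It took 11.9% of suffix 1 and 0.577% of suffix 6. If low UMI counts alone had set it apart, thinning every cell to 1000 UMIs would have dissolved it. After thinning, 63.8% of its 6770 remaining cells fell into 1 new cluster of 7801 cells, a Jaccard overlap of 0.42 between the bounds of 0.2 and 0.5 set for and against that explanation, so it stays open, and no biological explanation was tested. Its median number of genes at 1000 UMIs was 530, against 549 in other cells.

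The labels give a loading target of 4000 to 10000 cells per sample. The cells per suffix lay above it in 4 suffixes, within it in 3 and below it in 1. The 10% of cells with the highest doublet score in each suffix had a median of 4278 UMIs, against 2011 in the others.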
